A study of Mus musculus with 90 samples.

How the data were processed

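The series holds liver RNA-seq libraries of 90 mouse samples in 9 groups of 10, as 2 deposited tables of expected counts, 1 per experiment. Per the labels' protocols, total RNA was extracted from liver with a magnetic bead kit and DNase, mRNA was purified with beads, and strand-specific libraries were made and amplified by PCR. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17, reads were checked with FastQC, and the builds GRCm38 and mm10 were used. Before deposit the authors made the expected counts, per the file headers, as 1 value per Entrez gene and sample; the aligner, the counting program and the handling of reads shared by similar genes are not given in the sources used here. The sequences of the shRNAs and the vector dose are not given there either.

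Each table held 24475 genes, of which 24375 matched a symbol in the reference gene table and 5042 (experiment 1) and 5221 (experiment 2) were 0 in every library. Values with a fractional part made up 8.54% and 8.41% of the entries, and all values were rounded to whole counts before testing. No column was left out (0 not used). Groups came from the labels. Total counts were 20.8 M to 33.7 M (median 25.3 M) in experiment 1 and 8.9 M to 19.5 M (median 16.5 M) in experiment 2. Between any 2 libraries of a group, counts differed by more than Poisson noise, with a lowest chi-squared per degree of freedom of 14.85 and 7.94 in the 2 experiments; pairs across groups were not compared.

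Differential expression was tested with edgeR 4.0.16 in R 4.3.3, within each experiment and over all its groups, which then share 1 estimate of the spread. Genes were filtered by filterByExpr, leaving 13574 and 12847, libraries were scaled by TMM, dispersions were estimated robustly (common values 0.0471 and 0.0394, with 45 and 36 residual degrees of freedom), and contrasts were tested by the quasi-likelihood F test with Benjamini-Hochberg (BH) adjustment. A gene was called at an adjusted p under 0.05. Experiment 1 gave 4 contrasts with the control group and 3 with Gcgr KD. Experiment 2 gave 5 contrasts between its groups and the interaction.

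Before any count was read, 34 gene lists were fixed, 23 of pathways and 11 of cell type markers, with 665 members, of which 1 (Ahsp) had no match. Camera tested 33 of them, all but the pancreatic acinar markers, of which 1 member was tested, each against all other genes with an inter-gene correlation of 0.01, and again with an estimated correlation, BH-adjusted over the lists of a contrast; this p is given where the call is lost. Members were also counted over all genes and with p-values adjusted over the list alone. The amino acid catabolism score was the mean, over 53 tested members, of log2 CPM (TMM, prior count 2) minus its control mean. The Gcgr KD signature was the mean centred log2 CPM of genes up with Gcgr KD minus that of genes down, for genes called with at least a 1.5-fold change. Scores were compared by two-sided permutation tests with 100000 resamples, BH-adjusted over 8 and 4 comparisons.

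Genes named in the text were chosen by a rule fixed before any count was read: 7 genes of the receptor pathway; 13 genes of amino acid, glucose and hormone metabolism; the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 1, a named symbol and at least 9 of 10 libraries past the other group's median; and up to 3 members per direction of each list. Fold changes are not given for genes with near-zero counts in a group; counts are given instead. Sec23b, Ergic1, Rian and H19 are singled out beyond that rule in some contrasts, after their values were seen. Got1, Gls2, Tat and Sds with Gcgr mAb in Prkar1a KD also lie outside the rule. They were among the falls with Gcgr mAb in Control AAV.

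Knockdowns were compared by correlation of fold changes, covariance and shared calls. As they share control libraries, groups with no effect were simulated: counts of the 50 libraries were divided by their group mean and multiplied by the mean of all, and 3 groups of 10 were drawn from them at random, 20 times. An earlier simulation centred on the observed controls was replaced after its result was seen. Controls were also split by odd and even sample number. Short hairpins can lower transcripts that pair with 7 bases of their guide strand, so 7-mers of 3 prime UTRs were searched in a random part of the genes and tested in the rest with a one-sided Fisher's exact test. Splits of the samples were drawn 40 times per contrast. The number was cut from 50 for run time, after the result with 50 was seen.

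The scripts were tested on simulated counts with 200 changed genes. In the Gcgr KD simulation (13376 genes) 52% of genes with a log2 change of 0.32 and 78%, 98% and 100% of genes changed 1.5-, 2- and 4-fold were recovered, with 4.1% of calls false. In the Gcgr mAb simulation (12643 genes) 42%, 88%, 98% and 100% were recovered, with 6.3% false. Alternatives were RLE scaling, no filter, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, a replicate block, only the groups of a comparison, and, for scores, a median over genes, prior count 0.5 and no fold minimum. Leaving out libraries with a quality weight under 0.5, a covariate for male-biased liver genes and leaving out each library in turn were added after the data were seen. The covariate was the mean log2 CPM of the male-biased list in the same libraries. Members of that list changed with some treatments, so the covariate can take up part of a treatment effect. Positions are in GRCm38.p6.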

Results

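Liver RNA was sequenced in a pair of mouse experiments built around the glucagon receptor, a G protein-coupled receptor on hepatocytes that raises cAMP. In experiment 1, mice received AAV8, a virus that transduces the liver, carrying a short hairpin RNA (shRNA), and 10 libraries each came from a control group and from knockdown (KD) of Gcgr, of Gnas, of protein kinase A (PKA) and of Epac2. In experiment 2, a control AAV or Prkar1a KD, which lowers a regulatory subunit that holds PKA inactive, was combined with a control antibody or an antibody against the glucagon receptor (Gcgr mAb), again with 10 libraries in each of 4 groups. Total counts per library lay between 20.8 M and 33.7 M (median 25.3 M) in experiment 1 and between 8.9 M and 19.5 M (median 16.5 M) in experiment 2. The labels number the samples of a group without saying that each came from a separate mouse, so p-values measure the spread between these samples. Changes are given as log2 fold changes ± SE with n = 10 per group, and a gene is called at an adjusted p under 0.05 in edgeR's quasi-likelihood test.

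The targeted transcripts were measured first, in every library. Gcgr (Entrez gene 14527, chromosome 11, 120529185 to 120538989 in GRCm38.p6), the receptor gene, stood at 171 ± 22.2 CPM (mean ± SD, n = 10) in the experiment 1 controls and at 45.7 ± 6.01 CPM with Gcgr KD, where the libraries spanned 38.3 to 54.1 CPM against 146 to 218 CPM, a change of -1.91 ± 0.10 (adjusted p = 1.22e-20). Gnas (Entrez gene 14683, chromosome 2, 174284320 to 174346744), which encodes the stimulatory G protein alpha subunit, went from 361 ± 19.7 CPM to 51.9 ± 18.9 CPM with Gnas KD, a change of -2.80 ± 0.11 (adjusted p = 3.98e-26). The labels of PKA KD name no subunit, and both catalytic subunit genes fell: Prkaca (Entrez gene 18747, chromosome 8, 83972978 to 83996444) from 95.6 ± 6.21 CPM to 11.5 ± 5.14 CPM, and Prkacb (Entrez gene 18749, chromosome 3, 146729579 to 146812946) from 40.2 ± 2.84 CPM to 9.61 ± 2.25 CPM. Their changes were -3.06 ± 0.13 (adjusted p = 1.4e-24) and -2.06 ± 0.086 (adjusted p = 6.11e-25). Rapgef4 (Entrez gene 56508, chromosome 2, 71981215 to 72257474), the gene of the cAMP-activated exchange factor Epac2, went from 91.1 ± 15.5 CPM to 9.48 ± 3.7 CPM, a change of -3.27 ± 0.18 (adjusted p = 1.7e-19), while its paralog Rapgef3 (Entrez gene 223864, chromosome 15, 97744770 to 97768419) was at 0.11 ± 0.17 (adjusted p = 0.803). In experiment 2, Prkar1a (Entrez gene 19084, chromosome 11, 109649023 to 109669663) was at 123 ± 10.9 CPM in the control group, 113 ± 6.57 CPM with Gcgr mAb, 32.1 ± 2.21 CPM with Prkar1a KD and 33.8 ± 3.67 CPM with both. In each knockdown group, every library lay below every control library for the targeted genes. Gcgr mRNA did not differ with Gcgr mAb, at -0.02 ± 0.066 (adjusted p = 0.868).

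**Figure D1:**
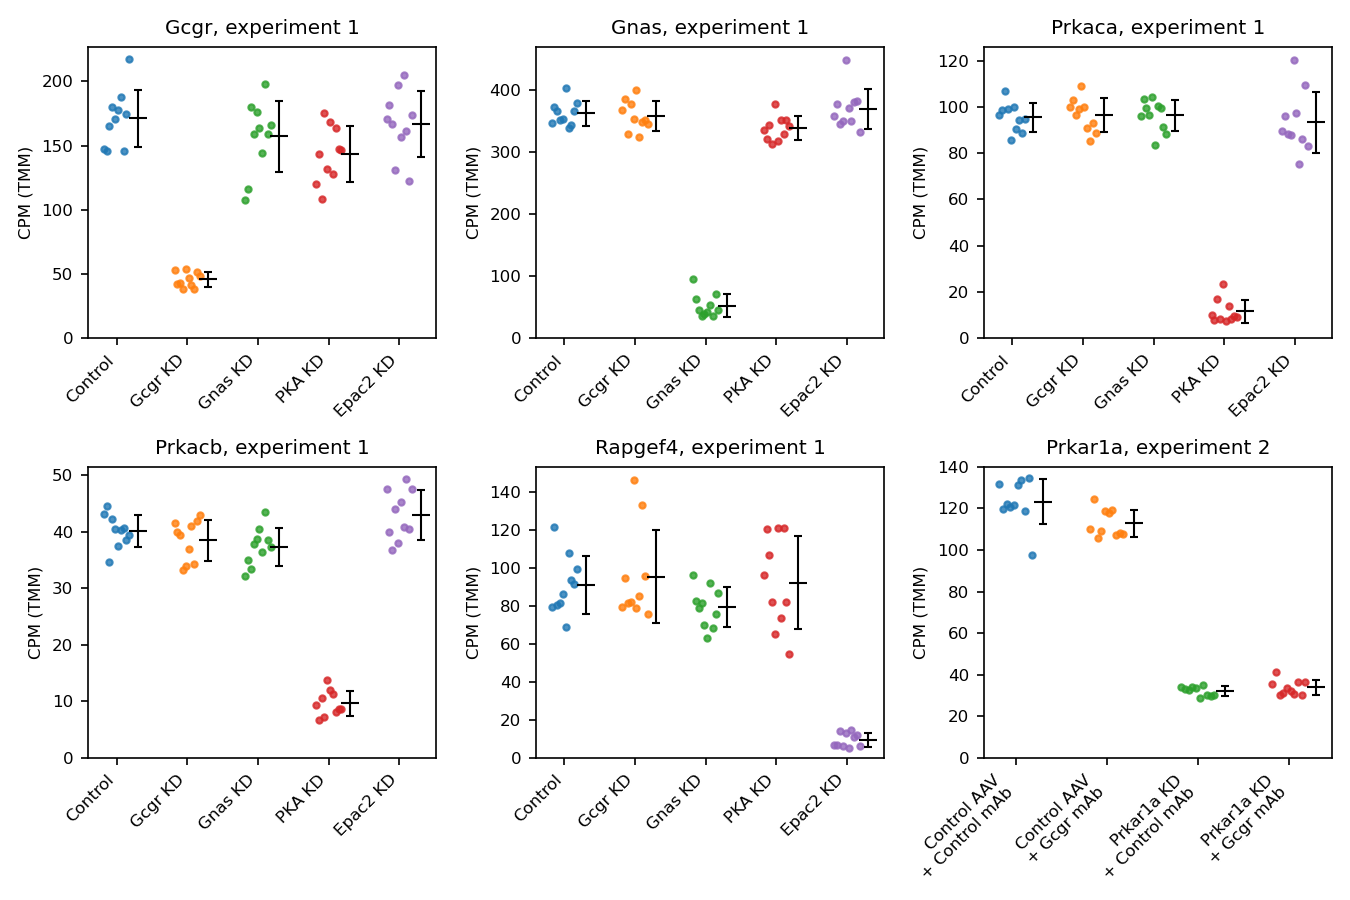
CPM (TMM-scaled) of the targeted genes in every library, with the group mean and SD as bars, for the 5 groups of experiment 1 and, for Prkar1a, the 4 groups of experiment 2. The 10 PKA KD libraries lay below all control libraries for both Prkaca and Prkacb.

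Genes of amino acid catabolism, gluconeogenesis and fatty acid oxidation were among those that fell when the receptor was lowered. With Gcgr KD, 393 genes rose and 588 fell of 13574 tested genes; with limma-voom 862 rose and 1062 fell, and with a covariate for male-biased genes 690 rose and 798 fell. Oat, an ornithine aminotransferase, changed by -1.29 ± 0.19 (adjusted p = 6.8e-06), Gls2, the liver glutaminase, by -0.69 ± 0.21 (adjusted p = 0.0346), and Pck1, which encodes the cytosolic enzyme that forms phosphoenolpyruvate in gluconeogenesis, by -0.64 ± 0.19 (adjusted p = 0.0327). Of the amino acid catabolism genes, 0 of 53 rose and 16 fell, and adjusted over the list alone 1 rose and 24 fell (camera adjusted p = 7.91e-13; adjusted p = 0.111 with an estimated correlation). Gnmt, which disposes of methyl groups from S-adenosylmethionine, was among the falls at -0.70 ± 0.13 (adjusted p = 0.000169). Among gluconeogenesis genes, 0 of 17 rose and 6 fell, and adjusted over the list alone 0 rose and 10 fell (camera adjusted p = 6.4e-05; adjusted p = 0.0705 with an estimated correlation). Among them were Fbp1 (-0.48) and Gpd1 (-0.47). In the urea cycle list, 0 of 10 rose and 3 fell, and adjusted over the list alone 0 rose and 6 fell (camera adjusted p = 9.01e-06; adjusted p = 0.111 with an estimated correlation). Examples were a fall of Arg1, the arginase that releases urea, at -0.63 ± 0.087 (adjusted p = 1.03e-06). For fatty acid oxidation and ketogenesis, 0 of 30 rose and 11 fell, and adjusted over the list alone 0 rose and 17 fell (camera adjusted p = 1.5e-12; adjusted p = 0.143 with an estimated correlation). Called members included Acot1 (-0.96), Acadl (-0.45) and Cpt2 (-0.43).

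Amino acid transporters went both ways with Gcgr KD: 1 of 24 rose and 3 fell, and adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.73). These included a rise of Slc7a5, a transporter of large neutral amino acids, at 0.58 and falls of Slc38a3 (-0.53), Slc38a4 (-0.50) and Slc38a2 (-0.36). Of the interferon response genes, 10 of 31 rose and 0 fell, and adjusted over the list alone 18 rose and 0 fell (camera adjusted p = 5.86e-11; adjusted p = 0.143 with an estimated correlation). Among them were Rsad2 (1.41), Mx1 (1.27) and Ifit1 (1.26). Among p53 target genes, 5 of 20 rose and 0 fell, and adjusted over the list alone 9 rose and 0 fell (camera adjusted p = 2.72e-06; adjusted p = 0.143 with an estimated correlation). Examples were Psrc1 (1.12) and Eda2r (1.07). The rises of largest size among genes meeting the naming rule were Cib3 (2.80), Sprr1a (2.53), H19 (2.24), Defb1 (2.16), Smpd3 (2.01), Orm3 (1.98), Cyp4a12b (1.72) and Ihh (1.68), where Orm3 and Cyp4a12b belong to gene families whose reads the counting could split. Besides Gcgr, the largest falls were Cfd (-1.91), Cidea (-1.90), Sec23b (-1.55), Elovl3 (-1.42), Ergic1 (-1.30), Oat (-1.29) and Ctcflos (-1.28). Sec23b, a coat protein of vesicles leaving the endoplasmic reticulum, and Ergic1, a protein of the early secretory route, did not fall with the other 3 knockdowns. Sec23b was at 0.00, 0.07 and 0.02 and Ergic1 at 0.17, 0.39 and 0.16 with Gnas, PKA and Epac2 KD. Among the genes named in advance, Cps1 at -0.31 ± 0.15 (adjusted p = 0.2) and Tat at -0.59 ± 0.21 (adjusted p = 0.0729) did not pass. Neither did Sds at -0.51 ± 0.27 (adjusted p = 0.281), G6pc at -0.36 ± 0.24 (adjusted p = 0.401) and Fgf21 at -0.60 ± 0.37 (adjusted p = 0.354). The 3 prime UTR 7-mer GCGTCCT, found in 1 random part of the genes, was present in 10.7% of the 291 falls among the remaining genes against 1.9% of the others (one-sided Fisher's exact test, adjusted p = 3.4e-13). Of the 16 amino acid catabolism falls, 1 carried it.

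With Gnas KD, genes of amino acid catabolism, fatty acid oxidation, lipogenesis and drug metabolism were among those that fell, and acute phase and cell cycle genes among those that rose. In all, 927 genes rose and 1130 fell. Tat, a tyrosine aminotransferase, changed by -0.97 ± 0.21 (adjusted p = 0.0009), Pck1 by -1.11 ± 0.19 (adjusted p = 5.59e-05), G6pc, the glucose-6-phosphatase that frees glucose, by -0.69 ± 0.24 (adjusted p = 0.0399) and the hormone gene Fgf21 by -1.33 ± 0.38 (adjusted p = 0.0123). In the amino acid catabolism list, 0 of 53 rose and 21 fell, and adjusted over the list alone 0 rose and 26 fell (camera adjusted p = 6.13e-11; adjusted p = 0.163 with an estimated correlation). Called members included Oat (-1.25), Got1 (-0.96) and Gls2 (-0.91). For gluconeogenesis, 1 of 17 rose and 10 fell, and adjusted over the list alone 1 rose and 12 fell (camera adjusted p = 1.71e-05; adjusted p = 0.0805 with an estimated correlation). Pck2, the mitochondrial counterpart of Pck1, was the rise at 0.44. Of the urea cycle genes, 0 of 10 rose and 5 fell, and adjusted over the list alone 0 rose and 5 fell (camera adjusted p = 5.97e-05; adjusted p = 0.163 with an estimated correlation). These included Arg1 (-0.89) and Ass1 (-0.62). Among fatty acid oxidation and ketogenesis genes, 0 of 30 rose and 19 fell, and adjusted over the list alone 0 rose and 23 fell (camera adjusted p = 5.32e-12; adjusted p = 0.163 with an estimated correlation). Among them were Cyp4a14 (-2.77), Acot1 (-1.65) and Cyp4a10 (-1.48). In the glycolysis and lipogenesis list, 0 of 27 rose and 10 fell, and adjusted over the list alone 0 rose and 12 fell (camera adjusted p = 3.23e-07; adjusted p = 0.339 with an estimated correlation). Examples were Elovl5 (-1.16), Acacb (-1.10) and Me1 (-1.09). For drug metabolism, 0 of 27 rose and 11 fell, and adjusted over the list alone 0 rose and 13 fell (camera adjusted p = 1.18e-05; adjusted p = 0.163 with an estimated correlation). Called members included Gsta2 (-1.67), Cyp2a5 (-1.27) and Gstm1 (-1.05).

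Among acute phase genes with Gnas KD, 9 of 26 rose and 0 fell, and adjusted over the list alone 12 rose and 0 fell (camera adjusted p = 3.71e-06; adjusted p = 0.381 with an estimated correlation). Saa1 and Saa2, near-identical serum amyloid genes whose reads could be split, were at 2.65 and 2.60, and Lcn2, an iron-binding protein of the acute phase, at 2.29. Of the cell cycle genes, 15 of 29 rose and 0 fell, and adjusted over the list alone 22 rose and 0 fell (camera adjusted p = 3.43e-07; adjusted p = 0.381 with an estimated correlation). These included Ccnb1 (1.24), Mcm6 (1.11) and Mki67 (1.09). The stellate cell markers moved with these groups: 5 of 12 rose and 0 fell, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.00328; adjusted p = 0.39 with an estimated correlation). Highest were the collagen genes Col1a1 (1.30), Col3a1 (1.02) and Col1a2 (0.97). By the naming rule the largest rises were Sprr1a (3.08), Cyp2d12 (2.89), Saa1 (2.65), Saa2 (2.60), Akr1b3 (2.45), Meg3 (2.45), Selenbp2 (2.39) and Pde6c (2.38). Besides Gnas, the largest falls were Acot3 (-3.39), Cyp4a14 (-2.77), Nipal1 (-2.37), Cyp2a4 (-2.24), Cfd (-2.21), Cyp17a1 (-2.03) and Mfsd2a (-1.98). Cyp2d12, Cyp2a4 and Selenbp2 have close paralogs, and Akr1b3 had 3 control libraries at 0. Sds at -0.74 ± 0.28 (adjusted p = 0.0597) and Cps1 at -0.20 ± 0.15 (adjusted p = 0.397) did not pass. The 3 prime UTR 7-mer GTTTCTG, found in 1 random part of the genes, was present in 28.6% of the 570 falls among the remaining genes against 16.9% of the others (one-sided Fisher's exact test, adjusted p = 5.83e-11). Of the 21 amino acid catabolism falls, 3 carried it.

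PKA KD changed more genes than the other knockdowns of experiment 1, as 2396 genes rose and 2005 fell. Fgf21 changed by -1.97 ± 0.39 (adjusted p = 7.11e-05), G6pc by -1.18 ± 0.24 (adjusted p = 0.000112), Gls2 by -1.16 ± 0.21 (adjusted p = 2.13e-05) and Tat by -1.14 ± 0.21 (adjusted p = 2.28e-05). Pck1 changed by -1.03 ± 0.19 (adjusted p = 3.04e-05), while Ppargc1a, a coactivator of gluconeogenic and mitochondrial genes, rose by 0.51 ± 0.14 (adjusted p = 0.00344). Among amino acid catabolism genes, 4 of 53 rose and 24 fell, and adjusted over the list alone 4 rose and 24 fell (camera adjusted p = 9.18e-05; adjusted p = 0.544 with an estimated correlation). The rises included Acmsd, of tryptophan catabolism, and Bhmt, a homocysteine methyltransferase, at 0.99 and 0.67. In the urea cycle list, 0 of 10 rose and 6 fell, and adjusted over the list alone 0 rose and 6 fell (camera adjusted p = 0.000799; adjusted p = 0.292 with an estimated correlation). Among them were Ass1 (-0.99) and Arg1 (-0.79). For gluconeogenesis, 2 of 17 rose and 6 fell, and adjusted over the list alone 2 rose and 6 fell (camera adjusted p = 0.0221; adjusted p = 0.336 with an estimated correlation). Of the fatty acid oxidation and ketogenesis genes, 1 of 30 rose and 20 fell, and adjusted over the list alone 1 rose and 21 fell (camera adjusted p = 2.7e-09; adjusted p = 0.292 with an estimated correlation). Examples were Ppara, the nuclear receptor that drives this pathway, at -1.16 and Crot at -0.97. Among glycolysis and lipogenesis genes, 1 of 27 rose and 13 fell, and adjusted over the list alone 1 rose and 15 fell (camera adjusted p = 0.000151; adjusted p = 0.551 with an estimated correlation). Called members included Scd1 (-2.28), Pnpla3 (-1.90) and Fads2 (-1.64). In the cholesterol synthesis list, 0 of 25 rose and 14 fell, and adjusted over the list alone 0 rose and 14 fell (camera adjusted p = 0.00325; adjusted p = 0.849 with an estimated correlation). These included Lss (-1.02) and Insig1 (-0.90).

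Of the interferon response genes with PKA KD, 14 of 31 rose and 1 fell, and adjusted over the list alone 16 rose and 4 fell (camera adjusted p = 0.00317; adjusted p = 0.748 with an estimated correlation). Among them were Rsad2 (1.40), Oasl2 (1.07) and Ifit1 (1.03) up and Stat2 down at -0.45. For acute CREB and cAMP response, 1 of 21 rose and 5 fell, and adjusted over the list alone 1 rose and 5 fell (camera adjusted p = 0.232). Examples were Lpin1 (-1.31) and Nr4a2 (-1.16). The list of amino acid stress genes gave 3 rises and 8 falls of 23, and the same numbers adjusted over the list alone (camera adjusted p = 0.0195; adjusted p = 0.292 with an estimated correlation). Called members included Aldh1l2 (-1.61) and Atf5 (-1.07) among the falls. By the naming rule the largest rises were Meg3 (5.26), H19 (4.97), Ly6c1 (4.92), Sult2a7 (4.37), Gipc2 (4.33), Cyp2d12 (4.21), Pde6c (4.06) and Pls1 (3.74). Meg3 and H19 are imprinted long non-coding RNAs, and Ly6c1, Sult2a7 and Cyp2d12 have close paralogs. The largest falls were Cfd (-3.75), Plin4 (-3.47), Cidea (-3.32), Mfsd2a (-3.24), Prkaca (-3.06), Cyb5r3 (-2.61), Prg4 (-2.48) and Phyh (-2.47). Beside these lipid-linked falls, adipocyte markers were lower (0 of 3 rose and 2 fell, and adjusted over the list alone 0 rose and 3 fell; camera adjusted p = 0.0143; adjusted p = 0.145 with an estimated correlation). The mitochondrial rRNA share of the counts was 0.068% ± 0.035 (SD) against 0.164% ± 0.021 in controls. The 3 prime UTR 7-mer AAGAGTT, found in 1 random part of the genes, was present in 20.9% of the 943 falls among the remaining genes against 9.9% of the others (one-sided Fisher's exact test, adjusted p = 3.59e-19). Of the 24 amino acid catabolism falls, 1 carried it.

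With Epac2 KD, genes of the interferon response were among those that fell. Few amino acid catabolism genes were called, as was the case over all tested genes (4.6% called). In all, 247 genes rose and 372 fell, while with limma-voom 477 rose and 551 fell, and with a covariate for male-biased genes 383 rose and 509 fell. Of the interferon response genes, 0 of 31 rose and 12 fell, and adjusted over the list alone 0 rose and 22 fell (camera adjusted p = 1.52e-19; adjusted p = 0.132 with an estimated correlation). These included Gbp3, a guanylate-binding protein, at -1.02, Ifit1 at -0.92 and the chemokine gene Cxcl10 at -0.88. Among amino acid catabolism genes, 2 of 53 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.418). Dbt, a subunit of the branched-chain ketoacid dehydrogenase, was the fall at -1.35 ± 0.11 (adjusted p = 9.31e-14), and Acmsd (1.14) and Mccc1 (0.23) were the rises. In the gluconeogenesis list, 0 of 17 rose and 3 fell, and adjusted over the list alone 0 rose and 3 fell (camera adjusted p = 0.126). Among them were Mdh1, the cytosolic malate dehydrogenase, at -0.95 ± 0.061 (adjusted p = 5.84e-17). For urea cycle, 0 of 10 and of the acute CREB and cAMP response genes 0 of 21 passed the test (0 and 0 adjusted over the list alone), with medians of 0.03 and 0.04. Fgf21 changed by -1.39 ± 0.38 (adjusted p = 0.0228). Pck1 at 0.16 ± 0.19 (adjusted p = 0.751), Tat at 0.30 ± 0.21 (adjusted p = 0.524) and G6pc at 0.21 ± 0.24 (adjusted p = 0.731) did not pass. By the naming rule the largest rises were Rpl37rt (3.79), Sult2a7 (2.23), Hamp2 (2.19), Orm3 (1.81), Fabp5 (1.63), Fam81a (1.36), Atp11a (1.34) and Snhg11 (1.27). Rpl37rt, a retrocopy with 3 control libraries at 0, Sult2a7, Hamp2 and Orm3 share sequence with relatives. Besides Rapgef4, the largest falls were Rec8 (-1.63), Ddah1 (-1.55), Cept1 (-1.40), Fgf21 (-1.39), Cntnap1 (-1.36), Dbt (-1.35) and Treh (-1.30). The 3 prime UTR 7-mer AATCTAA, found in 1 random part of the genes, was present in 37.4% of the 179 falls among the remaining genes against 6.9% of the others (one-sided Fisher's exact test, adjusted p = 1.65e-29). The amino acid catabolism fall, Dbt, carried it.

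A score of amino acid catabolism, the mean centred log2 CPM of 53 genes in each library, was set beside these counts. Against controls it differed by -0.26 ± 0.058 (SE) with Gcgr KD (permutation test, adjusted p = 0.000537), -0.30 ± 0.064 (SE) with Gnas KD (adjusted p = 0.000537) and -0.29 ± 0.053 (SE) with PKA KD (adjusted p = 0.000112). In each of these groups all 10 libraries lay below the control median. With Epac2 KD the difference was 0.06 ± 0.076 (SE) (permutation test, adjusted p = 0.425), with 5 of 10 libraries above the control median.

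**Figure D2:**
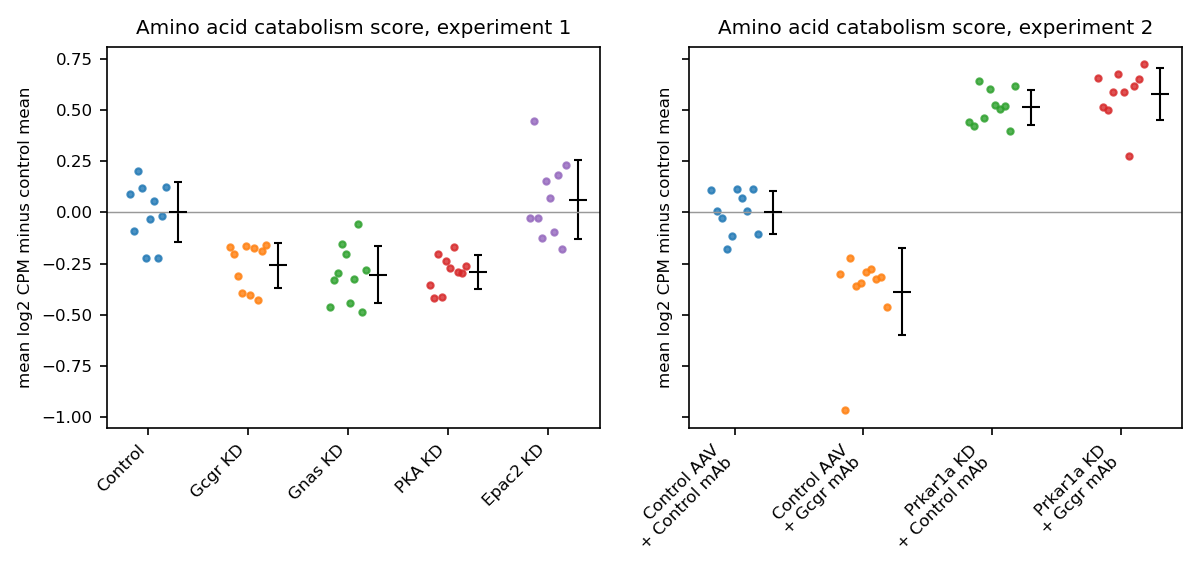
Amino acid catabolism score (mean centred log2 CPM of 53 genes, relative to the control group of the experiment) of every library, with group mean and SD as bars, in the 5 groups of experiment 1 and the 4 groups of experiment 2. All libraries of both Prkar1a KD groups lay above 0, and all libraries with Gcgr mAb in Control AAV lay at -0.22 or lower.

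Direct comparisons with Gcgr KD asked how each downstream knockdown differed from it, with any effects of either hairpin on other transcripts included. Between Gnas KD and Gcgr KD, 322 genes rose and 471 fell; with limma-voom 561 rose and 762 fell, and without low-weight libraries 529 rose and 705 fell. Of the amino acid catabolism genes, 1 of 53 rose and 2 fell, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.734). Of the interferon response genes in this comparison, 0 of 31 rose and 14 fell, and adjusted over the list alone 0 rose and 17 fell (camera adjusted p = 1.85e-10; adjusted p = 0.545 with an estimated correlation). Examples were Ifit1 (-1.33), Ifi44 (-1.29) and Rsad2 (-1.26). Among drug metabolism genes, 0 of 27 rose and 8 fell, and adjusted over the list alone 0 rose and 11 fell (camera adjusted p = 2.91e-08; adjusted p = 0.0789 with an estimated correlation). Genes higher with Gnas KD included Cyp2d12 (2.12), Pde6c (2.05), Meg3 (1.76), Sec23b (1.55), Ergic1 (1.47), Pik3c2g (1.37) and Rabac1 (1.30). Against controls, Sec23b, Ergic1 and Rabac1 were at 0.00, 0.17 and 0.08 with Gnas KD. With Gcgr KD they were at -1.55, -1.30 and -1.22, so these differences came mainly from falls with Gcgr KD. Lower ones were Acot3 (-2.05), Nipal1 (-1.78), Slc16a5 (-1.46), Gsta2 (-1.44), Rnf149 (-1.34) and Gstm1 (-1.30). Between PKA KD and Gcgr KD, 2346 genes rose and 1953 fell. Amino acid catabolism members went both ways, as 9 of 53 rose and 9 fell, and adjusted over the list alone 10 rose and 9 fell (camera adjusted p = 0.925). Called members included Got2 (0.54) and Bhmt (0.50) higher and Gpt2 (-0.77) and Amdhd1 (-0.76) lower. The largest differences were Meg3 (4.57), Sult2a7 (4.13), Ly6c1 (4.05), Pde6c (3.73), Cyp2d12 (3.44), Gipc2 (3.07), H4c8 (3.01) and Snhg11 (2.80). On the other side were Prg4 (-3.17), Plin4 (-2.71), Cyb5r3 (-2.70), Mfsd2a (-2.39), Chrna4 (-2.34), Pnpla3 (-2.33) and Phyh (-2.20).

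Between Epac2 KD and Gcgr KD, 1501 genes rose and 1319 fell. Among amino acid catabolism genes in this comparison, 31 of 53 rose and 3 fell, and adjusted over the list alone 35 rose and 4 fell (camera adjusted p = 9.1e-10; adjusted p = 0.599 with an estimated correlation). These included Oat (1.68), Got1 (1.18) and Gnmt (0.89), with Dbt lower at -1.15. Interferon response genes were lower, as 0 of 31 rose and 28 fell, and adjusted over the list alone 0 rose and 29 fell (camera adjusted p = 1.39e-29; adjusted p = 0.0201 with an estimated correlation). Among them were Rsad2 (-2.29), Ifit1 (-2.19) and Ifi44 (-1.80). In the cell cycle list, 1 of 29 rose and 19 fell, and adjusted over the list alone 1 rose and 20 fell (camera adjusted p = 1.59e-07; adjusted p = 0.599 with an estimated correlation). Examples were Ccnb1 (-1.70) and Cdc20 (-1.68) lower. Named by rule, the other large differences were Mup9 (3.06), Elovl3 (2.04), Cyp17a1 (1.87), Ugt1a9 (1.86) and Hamp2 (1.67) higher and Sprr1a (-3.01), Apoa4 (-2.16), Smpd3 (-2.08) and Mas1 (-1.81) lower. Mup9 and Ugt1a9 belong to families with shared sequence.

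Agreement between knockdowns was measured across 13574 genes, which are not independent replicates, and against the same 10 control libraries. Simulated groups with no effect gave a mean Pearson r of 0.53 (0.31 to 0.76 over 20 draws), a mean covariance of 0.0188 (0.0066 to 0.0374) and 0 genes called in both. For Gcgr KD and Gnas KD the values were r = 0.66, rho = 0.64 and a covariance of 0.0652 (0.0465 after subtracting the simulated mean), with 214 genes up and 288 down in both against 26.8 and 48.9 for independent lists, and 8 called in opposite directions against 72.9. For Gcgr KD and PKA KD they were r = 0.45, rho = 0.34 and a covariance of 0.0595 (0.0408 after subtracting the simulated mean), with 244 genes up and 284 down in both against 69.4 and 86.9 for independent lists, and 66 called in opposite directions against 162. Gnas KD and PKA KD gave r = 0.45, rho = 0.36 and a covariance of 0.0747 (0.0559 after subtracting the simulated mean), with 419 genes up and 508 down in both against 164 and 167 for independent lists, and 131 called in opposite directions against 336. Epac2 KD was set against the others in the same way. Against Gcgr KD it had r = 0.18, rho = 0.09 and a covariance of 0.0135 (-0.0053 after subtracting the simulated mean), with 28 genes up and 32 down in both against 7.2 and 16.1 for independent lists, and 41 called in opposite directions against 21.5. Against Gnas KD it had r = 0.22, rho = 0.13 and a covariance of 0.0203 (0.0015 after subtracting the simulated mean), with 52 genes up and 84 down in both against 16.9 and 31 for independent lists, and 47 called in opposite directions against 46. Against PKA KD it had r = 0.25, rho = 0.18 and a covariance of 0.0312 (0.0125 after subtracting the simulated mean), with 106 genes up and 96 down in both against 43.6 and 54.9 for independent lists, and 120 called in opposite directions against 102. With the controls split by odd and even number, so that no library was shared, r was 0.41 for Gcgr KD with Gnas KD, 0.27 for Gcgr KD with PKA KD, 0.29 for Gnas KD with PKA KD. It was -0.05, -0.01 and 0.10 for Epac2 KD with Gcgr KD, Gnas KD and PKA KD.

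Genes of amino acid catabolism, the urea cycle and gluconeogenesis were among those that fell when the antibody blocked the receptor. With Gcgr mAb in Control AAV mice, 375 genes rose and 677 fell of 12847 tested genes. Got1, a cytosolic aspartate aminotransferase, changed by -2.22 ± 0.099 (adjusted p = 2.27e-20), Gls2 by -1.56 ± 0.10 (adjusted p = 1.2e-14), Sds, which deaminates serine, by -1.49 ± 0.20 (adjusted p = 1.97e-06) and Pck1 by -1.27 ± 0.18 (adjusted p = 4.15e-06). The cationic amino acid transporter gene Slc7a2 changed by -1.07 ± 0.12 (adjusted p = 1.91e-08) and Tat by -0.80 ± 0.12 (adjusted p = 1.65e-05). For amino acid catabolism, 0 of 53 rose and 22 fell, and adjusted over the list alone 0 rose and 34 fell (camera adjusted p = 7.13e-27; adjusted p = 0.0177 with an estimated correlation). Of the urea cycle genes, 0 of 10 rose and 5 fell, and adjusted over the list alone 0 rose and 6 fell (camera adjusted p = 6.5e-13; adjusted p = 0.00161 with an estimated correlation). Called members included Ass1 (-0.97) and Arg1 (-0.68). Among gluconeogenesis genes, 0 of 17 rose and 8 fell, and adjusted over the list alone 0 rose and 10 fell (camera adjusted p = 4.87e-20; adjusted p = 4.7e-06 with an estimated correlation). These included a fall of Fbp1 (-0.91). In the fatty acid oxidation and ketogenesis list, 0 of 30 rose and 13 fell, and adjusted over the list alone 0 rose and 21 fell (camera adjusted p = 2.18e-15; adjusted p = 0.0177 with an estimated correlation). Among them were Acads (-0.42) and Eci1 (-0.37). Periportal zone genes, several shared with the lists above, were counted as well: 3 of 20 rose and 9 fell, and adjusted over the list alone 4 rose and 11 fell (camera adjusted p = 5.65e-11; adjusted p = 0.015 with an estimated correlation).

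Of the acute CREB and cAMP response genes with Gcgr mAb, 1 of 21 rose and 5 fell, and adjusted over the list alone 3 rose and 6 fell (camera adjusted p = 0.00343; adjusted p = 0.216 with an estimated correlation). Pde4b, a cAMP phosphodiesterase, and Nr4a2, a nuclear receptor induced by cAMP, were at -1.51 and -1.42. Fos rose by 1.47, and Kiss1, a secreted peptide gene, fell, with 4 of 10 libraries at 0 and 13 counts in all. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.21 ± 0.25 (adjusted p = 0.00164) and Rapgef4 by 0.56 ± 0.11 (adjusted p = 0.0008). Cps1 at -0.30 ± 0.14 (adjusted p = 0.182), G6pc at -0.73 ± 0.24 (adjusted p = 0.0537), Fgf21 at -0.24 ± 0.46 (adjusted p = 0.793) and Ppargc1a at -0.16 ± 0.17 (adjusted p = 0.599) did not pass. By the naming rule the largest rises were Mup11 (3.13), Selenbp2 (2.87), Cav1 (2.46), Mup19 (2.45), Smad9 (2.14), Mup16 (2.12), Mup2 (1.69) and Defb1 (1.66). The major urinary protein (Mup) genes are near-identical and uncertain individually. The largest falls were Mmd2 (-5.04), Cyp17a1 (-3.58), Gprc5b (-3.25), Cidea (-2.58), Cyp2a22 (-2.27), Got1 (-2.22) and Treh (-2.08) and Tmem266, which had 11 counts over the Gcgr mAb libraries. Fitted on the 20 libraries of this comparison alone, 241 genes rose and 367 fell. With limma-voom 666 rose and 1036 fell, and with a covariate for male-biased genes 732 rose and 752 fell. The best 3 prime UTR 7-mer of this comparison was in 5.1% of falls against 7.8% of other genes (one-sided Fisher's exact test, adjusted p = 0.999).

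Receptor knockdown and receptor antibody were compared across experiments that share no library. Over 12746 genes tested in both, fold changes correlated at r = 0.50 and rho = 0.50 across genes, with 74 genes up and 177 down in both, and 3 went opposite ways, against 11, 30.9 and 37 for independent lists. One-sided Fisher's exact tests gave adjusted p = 6.33e-41 for rises and 5.28e-90 for falls. Genes are not independent replicates, so these p-values do not measure the spread between libraries. When libraries were resampled within groups, the correlation of mean log2 CPM differences had an SD of 0.11. Of the genes called with Gcgr KD, 86.2% had the same sign with Gcgr mAb, against 68% of all genes. A signature of 203 genes from Gcgr KD (109 up and 94 down, called with a change of at least 1.5-fold) was scored in each library of experiment 2. It was higher with Gcgr mAb in Control AAV mice by 1.06 ± 0.16 (SE) (permutation test, adjusted p = 2e-05; the raw p of 1e-05 is the smallest that 100000 resamples can give), in 10 of 10 libraries. The Gcgr mAb library numbered 2 stood apart at 2.02 against 0.90 for the next, with an amino acid catabolism score of -0.97 against -0.46, and without low-weight libraries the signature difference was 0.95 (adjusted p = 0.00038). With Prkar1a KD alone the difference from controls was 0.16 ± 0.11 (SE) (adjusted p = 0.224). With Prkar1a KD and Gcgr mAb together it was 0.08 ± 0.097 (SE) (adjusted p = 0.429). Between Prkar1a KD and Control AAV, both with Gcgr mAb, it was -0.98 ± 0.17 (SE) (adjusted p = 2e-05). With a median over genes the Prkar1a KD difference was 0.26 (adjusted p = 0.0485). With no fold minimum these 4 differences were 0.50, -0.02, -0.07 and -0.57 in the order given (adjusted p = 2e-05, 0.737, 0.221 and 2e-05).

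**Figure D3:**
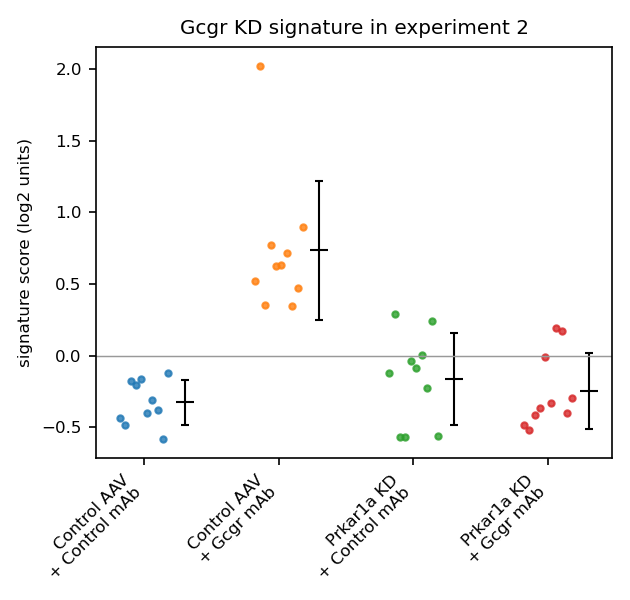
Score of the 203-gene Gcgr KD signature (log2 units) in every library of the 4 groups of experiment 2, with group mean and SD as bars. The Control AAV + Gcgr mAb libraries spanned 0.35 to 2.02, and the control group -0.58 to -0.12.

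With Prkar1a KD, genes of the cAMP response and the urea cycle were among those that rose, genes of lipid synthesis were among those that fell, and amino acid catabolism genes went both ways. In all, 3761 genes rose and 3462 fell against Control AAV, both with control antibody. Pck1 changed by 2.55 ± 0.19 (adjusted p = 1.31e-14), Tat by 2.53 ± 0.13 (adjusted p = 1.41e-19), Slc7a2 by 2.21 ± 0.12 (adjusted p = 1.9e-18) and Gls2 by 2.04 ± 0.10 (adjusted p = 1.59e-19). Cps1, the first enzyme of the urea cycle, changed by 1.39 ± 0.14 (adjusted p = 4.81e-11), G6pc by 1.53 ± 0.25 (adjusted p = 1.66e-06) and Ppargc1a by 1.76 ± 0.17 (adjusted p = 1.36e-11). Kiss1 changed by 3.38 ± 0.22 (adjusted p = 5.27e-16) and Igfbp1, an insulin-like growth factor binding protein, by 3.04 ± 0.40 (adjusted p = 3.33e-08). For amino acid catabolism, 28 of 53 rose and 13 fell, and adjusted over the list alone 28 rose and 13 fell (camera adjusted p = 2.39e-06; adjusted p = 0.41 with an estimated correlation). Examples were Acmsd (3.77) and Cth (2.45) up and Bhmt (-1.40) and Gcsh (-0.96) down. Of the urea cycle genes, 7 of 10 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 1.85e-06; adjusted p = 0.0651 with an estimated correlation). Called members included a rise of Asl (1.27). Among gluconeogenesis genes, 9 of 17 rose and 4 fell, and adjusted over the list alone 9 rose and 4 fell (camera adjusted p = 0.00502; adjusted p = 0.183 with an estimated correlation). The falls were led by Slc37a4, the glucose-6-phosphate transporter, at -1.12. In the acute CREB and cAMP response list, 14 of 21 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell (camera adjusted p = 1.03e-09; adjusted p = 0.00465 with an estimated correlation). These included Pde10a (4.26) and Nr4a1 (4.23) up. Among amino acid transporters, 12 of 24 rose and 3 fell, and adjusted over the list alone 12 rose and 3 fell (camera adjusted p = 0.00449; adjusted p = 0.0966 with an estimated correlation). Among them were Slc1a5 (2.27) and Slc38a2 (1.56).

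Every called glycolysis and lipogenesis gene and every called cholesterol synthesis gene fell with Prkar1a KD. Of the former, 0 of 27 rose and 22 fell, and adjusted over the list alone 0 rose and 22 fell (camera adjusted p = 2.82e-08; adjusted p = 0.183 with an estimated correlation). Examples were Thrsp, a regulator of lipogenesis, at -5.48, Scd1, the stearoyl-CoA desaturase, at -3.67 and Acacb at -3.31. Of the latter, 0 of 25 rose and 24 fell, and adjusted over the list alone 0 rose and 24 fell (camera adjusted p = 2.38e-09; adjusted p = 0.372 with an estimated correlation). Called members included Hmgcs1 (-3.66), Mvd (-3.09) and Fdps (-2.52). Fatty acid oxidation genes went both ways, as 9 of 30 rose and 17 fell, and adjusted over the list alone 9 rose and 17 fell (camera adjusted p = 0.00674; adjusted p = 0.521 with an estimated correlation). These included Acot1 (1.68) up and Vnn1 (-2.67) down. For drug metabolism, 5 of 27 rose and 18 fell, and adjusted over the list alone 5 rose and 18 fell (camera adjusted p = 0.000232; adjusted p = 0.183 with an estimated correlation). Among them were the cytochromes Cyp2b10 (-5.18), Cyp3a11 (-4.76) and Cyp2c54 (-4.42). Of the interferon response genes, 27 of 31 rose and 1 fell, and adjusted over the list alone 28 rose and 1 fell (camera adjusted p = 9.92e-09; adjusted p = 0.372 with an estimated correlation). Examples were Rsad2 (2.74) and Ifit1 (2.26). Among cell cycle genes, 20 of 30 rose and 0 fell, and adjusted over the list alone 22 rose and 0 fell (camera adjusted p = 0.00535; adjusted p = 0.767 with an estimated correlation). Called members included Plk1 (1.62) and Cdk1 (1.45). Acute phase genes went both ways (9 of 26 rose and 13 fell, and adjusted over the list alone 9 rose and 13 fell; camera adjusted p = 0.496). These included Orm1 at -3.04 and Saa2 at -2.30, both of families with shared sequence.

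Among the largest rises with Prkar1a KD were Rian (5.68), Tuba8 (5.52), Asns (5.10), Meg3 (4.88) and Jazf1 (4.84). Asns encodes asparagine synthetase and Rian and Meg3 are imprinted non-coding RNAs of the same locus. Pcdh20, Ren1, which encodes renin, and Col22a1 were also among them, with 6, 3 and 6 counts over the 10 control libraries, so no fold is given. Among the falls, Cidea, Orm3, Cfd and Chrna4 had 3, 2, 6 and 7 counts over the 10 Prkar1a KD libraries. Rarres1 was at -6.28, and Mup15, Mup16 and Mup19 passed the test but share reads. Erythroid markers fell, as 0 of 4 rose and 4 fell, and adjusted over the list alone 0 rose and 4 fell (camera adjusted p = 0.0624). For adipocyte markers, 0 of 3 rose and 3 fell, and adjusted over the list alone 0 rose and 3 fell (camera adjusted p = 0.00891; adjusted p = 0.0651 with an estimated correlation). Hepatocyte markers went both ways, as 4 of 12 rose and 7 fell, and adjusted over the list alone 4 rose and 7 fell (camera adjusted p = 0.379). Albumin took 2.16% ± 0.332 (SD) of counts against 5.36% ± 0.227, and mitochondrial rRNA 1.29% ± 0.259 against 0.571% ± 0.084. The best 3 prime UTR 7-mer of this comparison was in 1.1% of falls against 2.4% of other genes (one-sided Fisher's exact test, adjusted p = 0.999). Gcgr itself fell by 0.39 (adjusted p = 4.17e-06).

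With Prkar1a KD and Gcgr mAb combined, comparison with the control group gave a count of called genes in which 3334 rose and 3111 fell. Tat changed by 2.59 ± 0.13 (adjusted p = 8.36e-20), Pck1 by 2.54 ± 0.19 (adjusted p = 2.16e-14) and Slc7a2 by 2.34 ± 0.12 (adjusted p = 3.74e-19). Gls2 changed by 2.05 ± 0.10 (adjusted p = 1.42e-19) and Got1 by 2.12 ± 0.098 (adjusted p = 1.02e-20). In the amino acid catabolism list, 29 of 53 rose and 8 fell, and adjusted over the list alone 29 rose and 8 fell (camera adjusted p = 3.81e-10; adjusted p = 0.249 with an estimated correlation). For urea cycle, 8 of 10 rose and 0 fell, and adjusted over the list alone 8 rose and 0 fell (camera adjusted p = 2.44e-08; adjusted p = 0.0234 with an estimated correlation). Of the cholesterol synthesis genes, 0 of 25 rose and 18 fell, and adjusted over the list alone 0 rose and 18 fell (camera adjusted p = 8.78e-05; adjusted p = 0.589 with an estimated correlation). Among them were Hmgcs1 (-2.70), Mvd (-2.15) and Fdps (-1.71). By the naming rule, Rian (6.06), Tuba8 (5.26), Meg3 (5.22), Jazf1 (4.95) and Asns (4.81) were again among the rises, and Themis (-5.04) and Rarres1 (-4.97) among the falls.

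Prkar1a KD was also compared with Control AAV where both received Gcgr mAb, and here 3403 genes rose and 3416 fell. Got1 changed by 4.34 ± 0.11 (adjusted p = 3.15e-30), Pck1 by 3.81 ± 0.20 (adjusted p = 2.85e-19), Gls2 by 3.61 ± 0.11 (adjusted p = 3.94e-27) and Slc7a2 by 3.41 ± 0.13 (adjusted p = 2.99e-24). Tat changed by 3.39 ± 0.13 (adjusted p = 1.53e-23), Sds by 2.90 ± 0.21 (adjusted p = 1.7e-14) and Oat by 3.18 ± 0.22 (adjusted p = 3.58e-15). Among amino acid catabolism genes, 37 of 53 rose and 8 fell, and adjusted over the list alone 37 rose and 9 fell (camera adjusted p = 1.94e-23; adjusted p = 0.0326 with an estimated correlation). In the urea cycle list, 8 of 10 rose and 0 fell, and adjusted over the list alone 9 rose and 0 fell (camera adjusted p = 1.44e-15; adjusted p = 0.000327 with an estimated correlation). For gluconeogenesis, 10 of 17 rose and 3 fell, and adjusted over the list alone 11 rose and 3 fell (camera adjusted p = 4.38e-11; adjusted p = 0.000432 with an estimated correlation). Of the acute CREB and cAMP response genes, 15 of 21 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell (camera adjusted p = 4.38e-14; adjusted p = 0.000148 with an estimated correlation). Examples were Nr4a1 (4.53) and Pde4b (2.44). Other large rises were Mmd2 (8.44), Nptx1 (6.85), Tuba8 (6.60), Cyp17a1 (6.37) and Cyp2a4 (6.21), the last with a close paralog. Pcdh20 and Ren1 were at 0 in all 10 Control AAV + Gcgr mAb libraries. Kupffer cell markers held no rise (0 of 12 rose and 9 fell, and adjusted over the list alone 0 rose and 9 fell; camera adjusted p = 0.0553). Neither did stellate cell markers (0 of 12 rose and 7 fell, and adjusted over the list alone 0 rose and 7 fell; camera adjusted p = 0.172) or endothelial markers (0 of 12 rose and 11 fell, and adjusted over the list alone 0 rose and 11 fell; camera adjusted p = 0.00456; adjusted p = 0.57 with an estimated correlation). The amino acid catabolism score differed by 0.97 ± 0.078 (SE) in this comparison, and by -0.39 ± 0.075 (SE) with Gcgr mAb alone. It differed by 0.51 ± 0.043 (SE) with Prkar1a KD alone and by 0.58 ± 0.052 (SE) with both (permutation tests, adjusted p = 2e-05 each; the raw p of 1e-05 is the smallest that 100000 resamples can give).

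In mice with Prkar1a KD, Gcgr mAb gave 0 called genes in edgeR's quasi-likelihood test, where 846 genes had an unadjusted p under 0.05. DESeq2 called 0 and limma-voom 28. Got1 was at -0.05 ± 0.094 (adjusted p = 0.964), Gls2 at 0.01 ± 0.10 (adjusted p = 0.986), Tat at 0.06 ± 0.12 (adjusted p = 0.967) and Sds at 0.13 ± 0.20 (adjusted p = 0.951). Of the 53 amino acid catabolism genes, 0 passed over all genes and 0 adjusted over the list alone; their median was 0.07 (camera adjusted p = 0.000244; adjusted p = 0.68 with an estimated correlation). Cholesterol synthesis genes had a median of 0.56, with 21 of 25 higher when adjusted over the list alone (camera adjusted p = 1.92e-29; adjusted p = 0.155 with an estimated correlation). Of the 1052 genes called with Gcgr mAb in Control AAV mice, 378 kept their sign with Prkar1a KD and 1047 had a smaller change, which their choice for a change without Prkar1a KD favors by itself. Over all 12847 genes, 8245 had a smaller change with Prkar1a KD. Over 958 genes called with Gcgr KD, a choice made in other libraries, 734 did, with median absolute log2 fold changes of 0.18 without and 0.07 with Prkar1a KD.

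The difference itself was tested as the interaction of Prkar1a KD and Gcgr mAb. In 16 of 53 amino acid catabolism genes the antibody effect was more positive with Prkar1a KD and in 0 more negative, or 30 and 0 adjusted over the list alone (camera adjusted p = 2.26e-25; adjusted p = 0.0313 with an estimated correlation). Over all genes the interaction was positive for 352 and negative for 172. With limma-voom 919 were positive and 626 negative. The negative ones were 106 without a filter, 267 with DESeq2 and 281 with a covariate for male-biased genes. Got1 passed this test (adjusted p = 4.46e-15). Oat had an interaction of 1.81 ± 0.29 (adjusted p = 0.000123), Sds of 1.63 ± 0.28 (adjusted p = 0.000357), Gls2 of 1.57 ± 0.14 (adjusted p = 3.74e-10), Pck1 of 1.26 ± 0.25 (adjusted p = 0.00211) and Slc7a2 of 1.20 ± 0.17 (adjusted p = 6.5e-06). Gluconeogenesis genes were positive in 7 of 17 (camera adjusted p = 1.51e-14; adjusted p = 9.63e-05 with an estimated correlation). So were urea cycle genes in 4 of 10 (camera adjusted p = 8.46e-10; adjusted p = 0.01 with an estimated correlation) and fatty acid oxidation genes in 9 of 30 (camera adjusted p = 1.58e-10; adjusted p = 0.0698 with an estimated correlation). Adjusted over the list alone these were 8, 4 and 19. Interferon response genes were negative in 8 of 31, and in 20 adjusted over the list alone (camera adjusted p = 1.51e-14; adjusted p = 0.183 with an estimated correlation). The largest interactions by rule were Mmd2 (5.11), Cyp17a1 (3.77), Gprc5b (3.61), Eno1b (3.39), Nptx1 (2.56), Cyp2a22 (2.47) and Treh (2.45) upward and Selenbp2 (-2.67), Cav1 (-2.23), Smad9 (-1.95), Gvin1 (-1.83), Enho (-1.69), Cd14 (-1.63), Oas1g (-1.50) and Eif4ebp3 (-1.43) downward. The amino acid catabolism score had an interaction of 0.45 and the Gcgr KD signature of -1.14, each with p = 1e-05, the smallest that 100000 resamples can give.

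**Figure D4:**
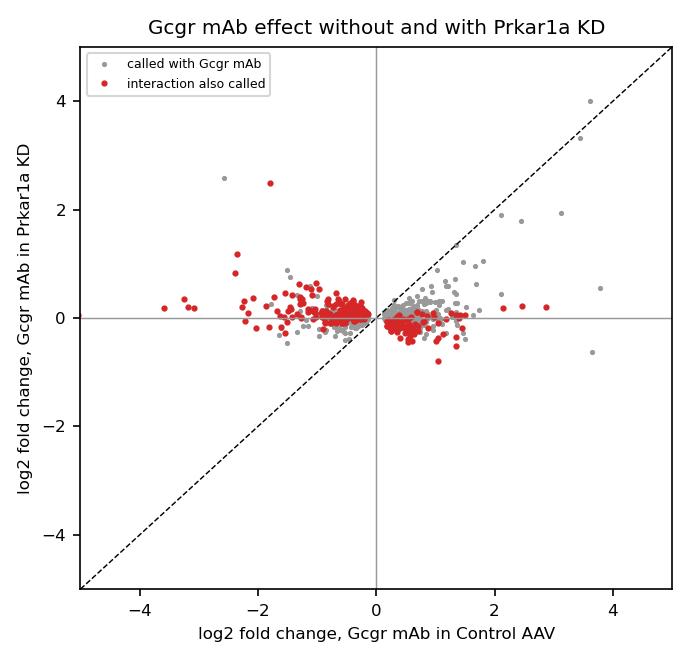
Log2 fold change of Gcgr mAb in Prkar1a KD mice (vertical) against that in Control AAV mice (horizontal) for the 1052 genes called in the latter, with equality as a dashed line and the 418 genes also called for the interaction in red; 1 gene lies outside the axes. The genes were chosen by their change on the horizontal axis, and 1047 of them had a smaller change on the vertical axis.

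**Figure D5:**
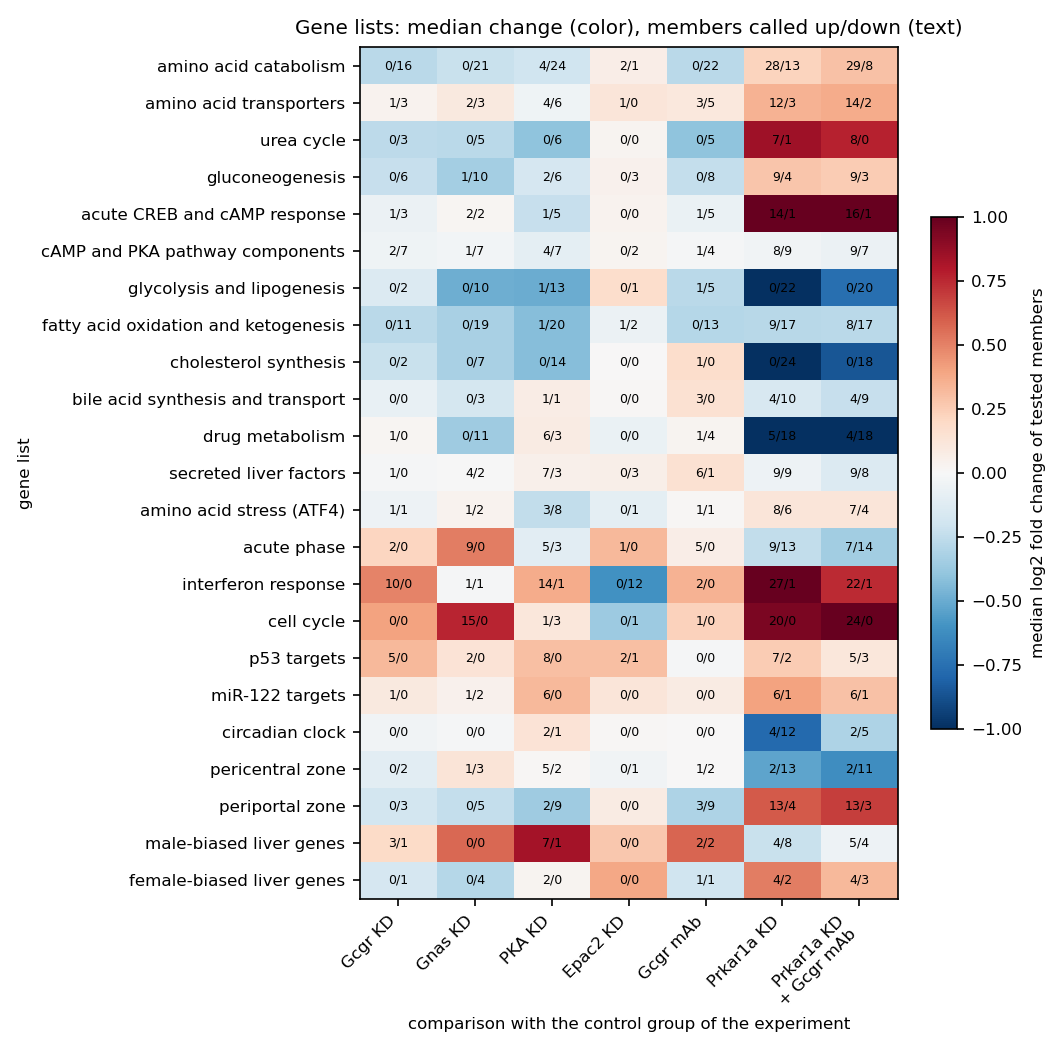
Median log2 fold change (color, capped at 1 in size) of 23 gene lists in 7 comparisons with the control group of the experiment, with the numbers of members called up and down as text. For amino acid catabolism these were 0/22 with Gcgr mAb and 28/13 with Prkar1a KD.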

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

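For the mitochondrial rRNA pattern below, the tests on mitochondrial mRNAs and on RNA without a tail were chosen only after the result was seen, as was the test on splits of the samples. Of 112 groups of values examined, 11 held a library far from the other 9, and chance gives about 1 in 20.

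In experiment 1, the Epac2 KD library numbered 5 (quality weight 0.421) had Gnas at 447.7 CPM against 381.9 for the next (ratio of the gap to the range 0.57) and 24.64% mitochondrial mRNA against 16.75% (ratio 0.532). A control library had 0.213% mitochondrial rRNA against 0.1745% (ratio 0.529). The PKA KD library numbered 5 (quality weight 0.415) had the largest total count, 33710000 against 26650000 (ratio 0.666), and the highest mitochondrial rRNA share, 0.1608% against 0.0864% (ratio 0.625). Its targeted genes were also the least lowered of the group, with Prkaca at 23.4 CPM and Prkacb at 13.8 CPM. The group means were 11.5 and 9.61 CPM.

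In experiment 2, Prkar1a was lowest in a control library at 97.78 CPM against 118.6 (ratio 0.562). With Gcgr mAb in Control AAV, the library numbered 2 (quality weight 0.162) stood apart in 3 measures: an amino acid catabolism score of -0.97 against -0.46 (ratio 0.678), a Gcgr KD signature of 2.02 against 0.90 (ratio 0.672) and 7.37% albumin against 5.12% (ratio 0.592). The library numbered 9 of that group had 20.16% mitochondrial mRNA against 16.44% (ratio 0.52). With Prkar1a KD and Gcgr mAb, the lowest amino acid catabolism score was 0.28 against 0.50 (ratio 0.501).

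The effect of Gcgr mAb differed with and without Prkar1a KD, by 0.4523 for the amino acid catabolism score and by -1.1443 for the Gcgr KD signature (permutation tests, p = 1e-05 each, the smallest that 100000 resamples can give), and 524 genes were called for this difference by edgeR's quasi-likelihood test.

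The rRNA transcripts mt-Rnr1 and mt-Rnr2 were lower with PKA KD (mean log2 fold change -1.44) and higher with Prkar1a KD (1.06). Less mitochondrial RNA in the tissue with PKA KD remains open, as the ratio of the median mRNA change to the rRNA change was 0.2659. With Prkar1a KD the ratio was -0.0298, so the mitochondrial mRNAs did not rise with the rRNA transcripts as shares of the counts. This argues against a larger share of mitochondrial RNA of both kinds there. Shares of counts do not give amounts in the tissue, and the mRNAs could have changed themselves. RNA without a tail was taken as replication-dependent histone, small nuclear and small nucleolar RNA genes. Their ratio was -0.9841 with PKA KD (16 genes, median 1.42, quartiles 0.24 and 2.65) and -0.0634 with Prkar1a KD (14 genes). A change of these genes themselves could hide an effect of selection. Poly(A) selection passing less RNA without a tail with PKA KD, or more with Prkar1a KD, therefore remains open. Library depth is excluded, as it gave a share of -0.0005 of the difference.

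Random splits of the same samples ask only how often a random grouping of them gives as many called genes. They were fitted on the groups of a comparison alone, except for the interaction. In each of the following the real grouping alone, 1 of 40, gave as many. That is the smallest share 40 splits can show, and it was not adjusted over the contrasts. Random splits thus seldom reached these counts, but chance is not excluded. A split that is uneven between the real groups keeps part of their difference. The highest other counts are therefore not counts without an effect, and the median of the other counts was 0 in every contrast. Real and highest other counts were 1287 and 1 for Gcgr KD, 2338 and 537 for Gnas KD, 4164 and 0 for PKA KD and 559 and 298 for Epac2 KD. They were 711 and 0 between Gnas KD and Gcgr KD, 3832 and 0 between PKA KD and Gcgr KD, and 2547 and 808 between Epac2 KD and Gcgr KD. In experiment 2 they were 608 and 369 for Gcgr mAb, 6958 and 3236 for Prkar1a KD, 6194 and 1 for both, and 6487 and 45 for Prkar1a KD with Gcgr mAb in each group. For the interaction all group labels of experiment 2 were shuffled, with a real count of 524 and a highest other of 1. This shuffling also broke up the Prkar1a KD effect, so it cannot decide about the interaction by itself. For Gcgr mAb with Prkar1a KD the real count was 0, which all 40 of 40 splits reach by construction (highest other 1), so splits decide nothing there.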

How the results depend on the processing

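Small changes were missed most in simulated counts: of genes with a log2 change of 0.32, 52% were recovered for Gcgr KD and 42% for Gcgr mAb, and of those changed 1.5-fold, 78% and 88%. Named results called in the main fit were compared between settings, 276 in all. Named results not called there, and genes named only as list members, were not compared. None of the 276 reversed in any setting. Calls were lost in 5 with DESeq2, 13 with limma-voom, 7 with the male-biased covariate and 9 without a filter. They were lost in 10 with the replicate block, 7 without low-weight libraries and 0 with RLE scaling, and in 7 of 257 with only the groups compared. The covariate, low-weight and leave-one-out settings were chosen after the data were seen.

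Total counts of called genes moved by more than 1.5 times only in these settings, whose cause was not tested. Limma-voom called 1924 with Gcgr KD, 1028 with Epac2 KD, 1323 between Gnas KD and Gcgr KD, 1702 with Gcgr mAb, 28 with Gcgr mAb in Prkar1a KD and 1545 for the interaction. The male-biased covariate gave 1488 with Gcgr KD, leaving out low-weight libraries 1234 between Gnas KD and Gcgr KD, and only the groups compared 608 with Gcgr mAb. By direction, with the total moved less, the covariate gave 732 rises and 752 falls with Gcgr mAb, 383 rises with Epac2 KD and 281 negative interactions, and negative interactions were 106 without a filter and 267 with DESeq2. With each library left out in turn, counts spanned 748 to 1101 (Gcgr KD), 1776 to 2244 (Gnas KD), 4114 to 4562 (PKA KD), 490 to 647 (Epac2 KD), 620 to 954, 3899 to 4630 and 2443 to 3010 (Gnas, PKA and Epac2 KD against Gcgr KD), 796 to 1333 (Gcgr mAb), 6968 to 7248 (Prkar1a KD), 6153 to 6506 (both), 6527 to 6881 (Prkar1a KD with Gcgr mAb in each group), 0 to 1 (Gcgr mAb in Prkar1a KD) and 389 to 702 (interaction).

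With no fold minimum the Gcgr KD signature was 0.50 with Gcgr mAb and -0.57 between the groups with Gcgr mAb, on the same side of the threshold. The Gcgr KD signature with Prkar1a KD was 0.26 with a median over genes (adjusted p = 0.0485), where it passed, and -0.02 with no fold minimum. With both treatments and no fold minimum it was -0.0684, of the other sign. The correlation of PKA KD with Epac2 KD was 0.14 among genes with an average log2 CPM of 3 or more. The cause was not tested in any of these. With an estimated correlation, camera adjusted p for amino acid catabolism was 0.111 (Gcgr KD), 0.163 (Gnas KD), 0.544 (PKA KD), 0.599 (Epac2 KD against Gcgr KD), 0.41 (Prkar1a KD), 0.249 (both) and 0.68 (Gcgr mAb in Prkar1a KD). Of 33 lists, those called with the preset correlation and with the estimate were 16 and 1 (Gcgr KD), 16 and 0 (Gnas KD), 13 and 1 (PKA KD), 3 and 0 (Epac2 KD), 14 and 5 (Gcgr mAb), 14 and 1 (Prkar1a KD) and 11 and 4 (interaction).

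The labels do not say that a number marks shared samples. Deviations of samples with the same number correlated at 0.0381 and 0.0374 in the 2 experiments (other pairs -0.0032 and -0.002), with means per number from -0.0633 to 0.323 (number 10) and from -0.0626 to 0.2104 (number 10). Single pairs went from -0.5338 to 0.6733 and from -0.412 to 0.5305, so the numbers were not taken as pairs, and 7 of 50 and 5 of 40 samples correlated best with their own number. With the replicate block, called genes were 1017, 2050, 4481 and 639 for Gcgr, Gnas, PKA and Epac2 KD, 792, 4347 and 2902 for Gnas, PKA and Epac2 KD against Gcgr KD, and 1039, 7212, 6490, 6813, 0 and 477 for Gcgr mAb, Prkar1a KD, both, Prkar1a KD with Gcgr mAb in each group, Gcgr mAb in Prkar1a KD and the interaction.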

Other observations

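With Prkar1a KD, genes of the pericentral zone, the part of the lobule around the central vein, were among those that changed: 2 of 20 rose and 13 fell, and adjusted over the list alone 2 rose and 13 fell (camera adjusted p = 0.000397; adjusted p = 0.41 with an estimated correlation). Glul, a glutamine synthetase, was at -2.89, and Cyp1a2 at -2.22. Circadian clock genes went both ways, as 4 of 20 rose and 12 fell, and adjusted over the list alone 5 rose and 12 fell (camera adjusted p = 0.0978); Arntl, an activator of the clock, was at 1.84, and Bhlhe41, Per3 and Dbp at -3.41, -2.42 and -2.41. The labels give no time of sampling. Bile acid genes in the same comparison gave 4 of 21 rose and 10 fell, and adjusted over the list alone 4 rose and 10 fell (camera adjusted p = 0.197). Of secreted liver factors, 9 of 27 rose and 9 fell, and adjusted over the list alone 9 rose and 9 fell (camera adjusted p = 0.59), with Fst, a follistatin, at 4.25 and Inhbe at -2.24.

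The pancreatic acinar marker tested, Cela1, was at -1.35 with Prkar1a KD and 1.35 with Gcgr mAb. Sex-biased genes also moved. Of the male-biased liver genes, 4 of 16 rose and 8 fell, and adjusted over the list alone 4 rose and 8 fell (camera adjusted p = 0.706) with Prkar1a KD and 2 of 16 rose and 2 fell, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.014; adjusted p = 0.549 with an estimated correlation) with Gcgr mAb. Of the female-biased liver genes, 4 of 9 rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.229) with Prkar1a KD. Targets of miR-122, the most abundant liver microRNA, were counted because hairpins can compete with it. With Gcgr KD 1 of 12 rose and 0 fell, and adjusted over the list alone 1 rose and 0 fell (camera adjusted p = 0.0565), with Gnas KD 1 of 12 rose and 2 fell, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.997), with PKA KD 6 of 12 rose and 0 fell, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.018; adjusted p = 0.252 with an estimated correlation) and with Epac2 KD 0 of 12 rose and 0 fell, and adjusted over the list alone 1 rose and 0 fell (camera adjusted p = 0.181).

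In the patterns below, the tests on Gnas KD and on endothelial and stellate markers were chosen only after the result was seen.

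Of the genes that fell at least 1.5-fold with Gcgr KD, 23, including Sec23b and Ergic1, fell by much less or not at all with Gcgr mAb (medians -0.73 and -0.03), and 1 of them, Cfd, rose (1.35). Pairing of the shRNA with 3 prime UTRs could lower them: the 7-mer GCGTCCT, found on other genes, was present in 9 of 21 searched (42.9% against 2.3% of others; one-sided Fisher's exact test, p = 4.45e-10), which this explanation predicts. Another explanation is a response to lost receptor signaling that only the animals of experiment 1 had. Their median with Gnas KD was -0.085 (quartiles -0.24 and 0.04). This argues against such a response through Gnas for the group as a whole. It does not for the 4 that fell there too, such as Cfd (-2.21). A response by a route other than Gnas was not tested and remains open. The sequence of the hairpin is not given in the sources used here, so the 7-mer was not compared with it.

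Meg3 and Rian were higher with PKA KD, which lowers catalytic subunits, and with Prkar1a KD, which lowers a regulatory subunit (Meg3 41.7 against 1.02 CPM, and 58.4 against 1.75 CPM). More endothelial or stellate cells in the samples are excluded, as stellate and endothelial marker medians were -0.0854 and -0.1721 with PKA KD and -0.0977 and -0.2119 with Prkar1a KD. A few libraries with very high values are excluded too, as 20 of 20 knockdown libraries lay above the highest control. Meg3 was at 1.75, 5.66 and 1.78 CPM with Gcgr, Gnas and Epac2 KD, and an effect of the vector was not tested.

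H19 in the Gcgr mAb group had a mean of 6.50 CPM, with 48.2 CPM in the library numbered 2 and 0.25 to 4.35 CPM in the other 9, against a control mean of 0.51 CPM. The Prkar1a KD + Gcgr mAb group had a mean of 5.01 CPM. There too the library numbered 2 was highest, at 41.1 CPM against 3.97 CPM for the next.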
